A study of Serapias vomeracea and Serapias vomeracea
Tulasnella calospora with 6 samples.

How the data were processed

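RNA was sequenced from 3 asymbiotic and 3 mycorrhizal protocorm samples of Serapias vomeracea. Per the labels' protocols, total RNA was extracted with a CTAB buffer and libraries were made with standard Illumina protocols. The series design text states that reads of 150 bp were made on a HiSeq2500 and that a reference was assembled de novo with Trinity from the asymbiotic reads. Reads of all samples were then aligned to it. The same text states that the mycorrhizal reads come from tissue of both plant and fungus and were analysed on the plant side. The aligner, the counting tool, their versions, the read filters and the treatment of strand are not given in the sources used here.

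The authors deposited 1 table per library, with 3 values for each contig. Per the file headers, these are the unique read count, the total read count and the RPKM (reads relative to contig length and library total). The counts are whole numbers and not normalized. By its name, the total also includes reads that are not unique to a contig, and how these were shared out is not given in the sources used here. The deposited RPKM was checked against the total reads: it gave the same contig length in every library, within 0.01 bp of a whole number for 100% of the 188302 contigs with a read, from 201 to 15392 bp. The lengths given here come from that relation. A further 16947 contigs had no read in any library. All tables list the same 205249 contigs, each with an identifier and none with a gene name. The test, its alternatives and the rule for naming contigs were set before the data were examined, as were lists of gene functions. These lists could not be applied without gene names, and no gene list was tested. Identifiers alone are given for the 2 contigs with the largest rise and the 2 with the largest fall, among those with an adjusted p under 0.05, no overlap between the groups and a mean of at least 10 reads per library in the lower group.

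Library totals ranged from 87991285 to 216364014 total reads, of which 51.4% to 55.7% were unique. A count of 0 allows up to 3 reads, which is 0.0139 to 0.0341 CPM depending on the library. Such floors cover counting error alone, since reads without molecular identifiers are not independent molecules. Total reads were taken for the test when the columns were known and before any test was run. Group CPM of the named contigs are scaled by the TMM factors, and those of contigs read in 1 group alone are not. Contigs were kept by edgeR's filterByExpr, which left 93242 of them, and libraries were scaled by TMM factors between 0.923 and 1.216. The main test was edgeR's quasi-likelihood F-test with robust estimation (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with no covariate and Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change was taken as the fold change divided by the square root of F. The common dispersion was 2.06, a coefficient of variation of 1.43 between replicates. Values per library were compared by two-sided exact permutation tests (scipy 1.17.1), which cannot go below p = 0.1 here. Of 13 measures computed per library, 4 were adjusted together, and the test of the most abundant contig's share was added after the data had been seen. Equal depth was made by drawing 87991285 reads per library without replacement. Figures were drawn with matplotlib 3.10.9.

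Replicates differed by far more than sampling noise, with a chi-square per degree of freedom between 80.0 and 755 within the groups, so no library was counted as a copy of another. The labels number the replicates 1 to 3 in both groups and state no shared day, batch or plate for a number, so the test has no replicate block.

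The test was checked on simulated counts drawn from the real means and library sizes with 200 contigs changed, at the real dispersions or at 0.1. At a dispersion of 0.1, edgeR called 84% of the 4-fold and 100% of the 16-fold changes among 92445 contigs tested, and 9 of its 193 calls were unchanged contigs. At the real dispersions, with changes placed in contigs of at least 10 CPM, it called 2% of the 4-fold and 69% of the 16-fold changes among 75709 contigs, and 27 of its 98 calls were contigs that had not been changed. DESeq2 (version 1.42.0) called 6% and 81% there, and 766 of its 853 calls were unchanged contigs. Limma-voom called 6% and 61%, and 25 of its 92 calls were unchanged contigs. With changes placed in contigs of any abundance, among 75569 tested, edgeR called 0% of the 4-fold and 1.5% of the 16-fold changes, and 7 of its 8 calls were unchanged contigs. DESeq2 called 4.8% and 36.8% there, with 740 unchanged contigs among 769 calls, and limma-voom made 0 calls. This last simulation was run first, and the other 2 were added after it had recovered almost none of the changes.

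The alternatives covered the scaling, the filter on low counts, the tool, the replicate block, each library left out in turn, a fold threshold, sums per Trinity gene and cluster, the robust option and equal depth. Unique reads, contigs of at least 500 bp, sample quality weights, the loss of mycorrhizal replicate 3 and asymbiotic replicate 2 together, and the removal of the cluster with the most abundant contig were added after the data had been seen. No reference genome was used here, so no coordinates are given.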

Results

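Gene expression was compared between protocorms of Serapias vomeracea, a terrestrial Mediterranean orchid, grown with or without the mycorrhizal fungus Tulasnella calospora. A protocorm is the small tuber-like body that an orchid embryo forms after germination, before shoots and roots. It depends on a fungus for carbon in nature. Both kinds of protocorm were taken at the stage that the labels call P2, in darkness at 20 °C and without chlorophyll. The comparison asks which plant transcripts differ in abundance when the fungus lives in the tissue. The mycorrhizal protocorms grew on oat medium with the fungus and the asymbiotic ones on a modified BM1 medium, so the groups differ in medium as well as in the fungus. Each group had 3 libraries, which the labels call biological replicates.

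Reads had been counted on 205249 contigs of a transcript assembly, which fall into 159127 Trinity genes. The assembler Trinity calls a set of contigs that share sequence a gene, and its contigs the gene's isoforms. The files give contig identifiers without gene names, so no gene function or pathway is reported. Abundance is given as CPM, a contig's reads relative to the total of its library. The asymbiotic libraries held 109869317, 87991285 and 102985675 reads in replicates 1 to 3. The mycorrhizal libraries held 216364014, 197549611 and 174635344 reads.

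Mycorrhizal protocorms differed from asymbiotic ones in 843 contigs, of which 611 were higher and 232 lower in the mycorrhizal libraries. The mycorrhizal tissue held both plant and fungus, and plant and fungal contigs were not told apart here. The contigs that were higher took up 0.740% ± 0.0113 (SD, n = 3) of the reads in asymbiotic protocorms and 8.80% ± 1.01 (SD, n = 3) in mycorrhizal ones. Those that were lower went from 10.7% ± 0.529 to 3.17% ± 0.419 of the reads (SD, n = 3 each). These shares describe contigs chosen by the same test. The median change was 21.8-fold among the contigs that were higher and 5.17-fold among those that were lower. These medians too describe contigs chosen by the test, so they depend on which changes it could call. The calls are from edgeR's quasi-likelihood test on 93242 contigs at a Benjamini-Hochberg adjusted p under 0.05, and the 2 groups' libraries did not overlap in any of the 843. Among all contigs tested, 20.4% showed no overlap, against the 10% that chance gives for 3 against 3. In counts simulated at the real dispersions, some edgeR calls were contigs that had not been changed. They were 27 of 98 calls when changes were placed in contigs of at least 10 CPM, and 7 of 8 at any abundance. Both are a larger share than the threshold sets. A contig had the same dispersion in all simulated libraries, without the missing reads of single libraries. These shares are therefore not an error rate of the 843 calls. The number of calls also depended on single libraries. Without mycorrhizal replicate 3, which had reads on the fewest contigs, the test called 1176 contigs higher and 721 lower, and 811 of the 843 were called again in the same direction. Without mycorrhizal replicate 2 it called 381 higher and 198 lower, with 515 of the 843 called again in the same direction. Without asymbiotic replicate 2 it called 416 and 100, with 433 called again. Leaving out both asymbiotic replicate 2 and mycorrhizal replicate 3 gave 96 and 16, with 91 called again. The split between higher and lower calls depended on the tool, with DESeq2 calling 1831 higher and 2176 lower and limma-voom 206 higher and 305 lower. Limma-voom with sample quality weights, added after the data had been seen, called 1461 higher and 654 lower.

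The strongest rise among called contigs with a mean of at least 10 reads per library in the lower group was that of TRINITY_DN70602_c0_g1_i2, a contig of 745 bp. It went from 0.158 ± 0.152 CPM in asymbiotic to 589 ± 432 CPM in mycorrhizal protocorms (SD, n = 3 each), a log2 fold change of 11.85 ± 1.63 (SE, edgeR adjusted p = 0.0289). Its asymbiotic libraries held 33, 0 and 16 reads, and the mycorrhizal ones 87182, 200710 and 53771. Unique reads made up 0.476% of its total, so its count depends on how the other reads were shared among contigs. TRINITY_DN52117_c0_g1_i1, 279 bp long, was next, at 0.132 ± 0.176 CPM in asymbiotic and 467 ± 382 CPM in mycorrhizal protocorms (SD, n = 3 each). Its log2 fold change was 11.76 ± 1.76 (SE, edgeR adjusted p = 0.0398), and all of its reads, 100%, were unique. Asymbiotic replicate 2 had no read of either contig, and a count of 0 in that library allows up to 0.0341 CPM. Both rises lost the call when certain libraries were left out, while the log2 fold change stayed between 11.03 and 12.75 for the first and between 10.82 and 13.80 for the second. For the first, the edgeR adjusted p was 0.535 without asymbiotic replicate 1, 0.725 without asymbiotic replicate 3, 0.281 without mycorrhizal replicate 1 and 0.436 without mycorrhizal replicate 2. For the second, no library could be left out with the call kept, and the edgeR adjusted p lay between 0.0636 (without mycorrhizal replicate 3) and 0.761 (without asymbiotic replicate 3). On unique reads neither rise was called, with log2 fold changes of 11.64 in both and edgeR adjusted p of 0.0689 and 0.194.

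By the same rule, the deepest fall was that of TRINITY_DN79417_c7_g5_i1, a contig of 380 bp with 51.1% unique reads. It stood at 46.7 ± 31.8 CPM in asymbiotic and 0.0552 ± 0.0128 CPM in mycorrhizal protocorms (SD, n = 3 each). Its log2 fold change was -9.70 ± 0.87 (SE, edgeR adjusted p = 0.00091). TRINITY_DN71602_c0_g1_i1, 1626 bp long, fell from 64.0 ± 14.2 CPM to 0.0875 ± 0.0509 CPM (SD, n = 3 each). Its log2 fold change was -9.50 ± 0.70 (SE, edgeR adjusted p = 0.000301), with 9.59% of its reads unique. On unique reads, the log2 fold changes of the 2 falling contigs were -9.86 and -12.85, and both were called. The first of the rising contigs lost its call under 10 of 23 other settings and the second under 13 of 22. The first of the falling contigs lost its call under 3 of 22 and the second under none of 23.

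**Figure D1:**
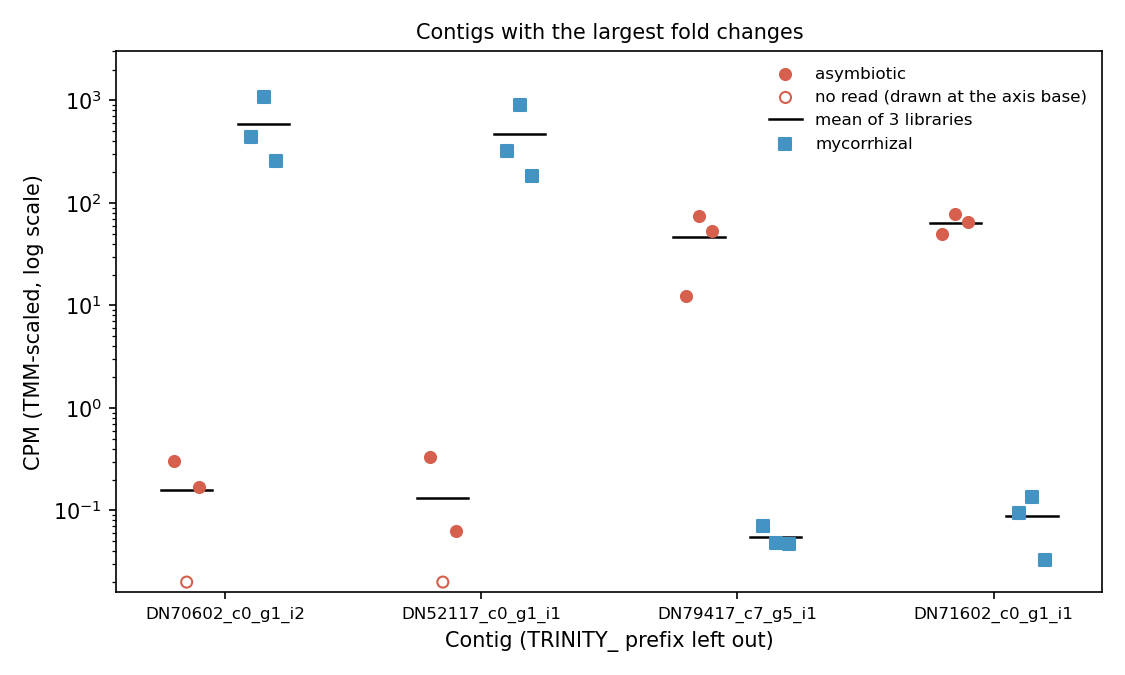
Abundance of the 4 contigs in each library, in CPM on a log axis. Points are single libraries (3 per group), lines are group means and open points mark libraries with no read. The contigs were chosen among those without overlap between the groups, so the libraries of the 2 groups lie apart in each. TRINITY_DN71602_c0_g1_i1 stood at 64.0 CPM in asymbiotic and 0.0875 CPM in mycorrhizal protocorms on average.

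At least a 4-fold change was found for 559 of the 611 contigs that were higher and for 138 of the 232 that were lower. At least a 16-fold change was found for 343 and 69 of them. For these counts, contigs with no read in a group were set to the bound that 3 reads per library give. In the simulations at the real dispersions, edgeR called 2% of 4-fold and 69% of 16-fold changes in contigs of at least 10 CPM. Smaller changes and those of less abundant contigs were thus mostly out of reach of the test there. Of the 1570 contigs at a mean of 100 CPM or more, 109 were higher and 93 lower, together 12.9%. Of the 12740 contigs between 10 and 100 CPM, 436 were higher and 92 lower. Between 1 and 10 CPM the numbers were 66 and 47 of 32759. Among the 46173 contigs under 1 CPM edgeR called 0, while DESeq2 called 1447 and limma-voom 4. Of these contigs, 1780 had an unadjusted edgeR p under 0.05, fewer than the share of 0.05 expected without any difference. The median length was 1253 bp among contigs that were lower, 845 bp among those that were higher and 682 bp among those not called.

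**Figure D2:**
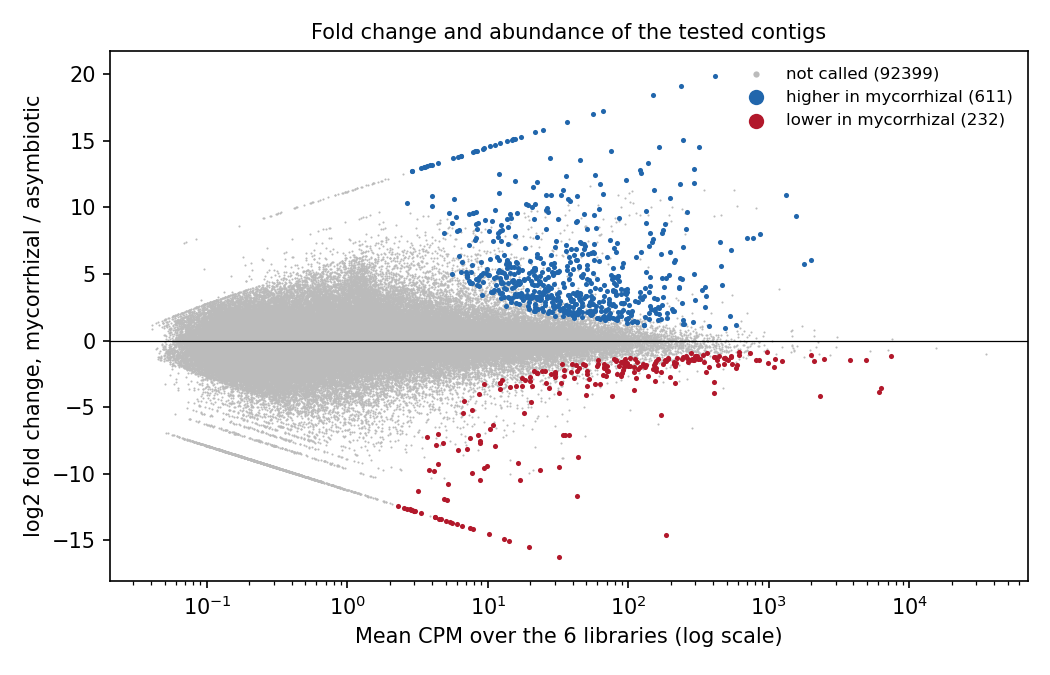
Each point is 1 of the 93242 tested contigs, with its mean CPM over the 6 libraries on a log axis and its log2 fold change between mycorrhizal and asymbiotic protocorms. Blue points are the 611 contigs called higher, red points the 232 called lower and grey points the rest. Contigs on the straight outer lines had no read in 1 group and their plotted fold depends on the prior count.

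The 100 most abundant contigs of asymbiotic protocorms held 24.4% ± 1.09 of the asymbiotic and 13.8% ± 4.28 of the mycorrhizal reads (SD, n = 3 each). Those of mycorrhizal protocorms held 21.2% ± 0.875 of the asymbiotic and 17.2% ± 4.27 of the mycorrhizal reads (SD, n = 3 each). Each list was chosen for its abundance in its own group. Of the 100 leading contigs of asymbiotic protocorms, 32 were lower in mycorrhizal protocorms. None of the 100 was called higher by edgeR. Of the 12 with a positive edgeR fold change, none was called higher by DESeq2 or limma-voom. Among those 12, 1 had an unadjusted edgeR p under 0.05. Of the 100 most abundant contigs of mycorrhizal protocorms, 20 were higher and 11 lower. The lists of the 2 groups shared 57 contigs. Single libraries shared 83 to 90 of their 100 leading contigs within the asymbiotic group, 68 to 77 within the mycorrhizal group and 50 to 56 between the groups. Over all 93242 tested contigs, each library's log2 CPM correlated best with another library of its own group, across contigs, which are not independent replicates. The margin was small for mycorrhizal replicate 3, at r = 0.59 with mycorrhizal replicate 2 and 0.58 with asymbiotic replicate 1. Within the groups r lay between 0.58 and 0.80, and between them from 0.52 to 0.71. The first principal component (49.2% of the variance) set mycorrhizal replicate 3 apart from the other libraries and the second (24.3%) asymbiotic replicate 2. The share of reads on each library's own 100 most abundant contigs was 24.5% ± 1.05 in asymbiotic and 17.6% ± 4.12 in mycorrhizal protocorms (SD, n = 3 each; two-sided exact permutation p = 0.1, 0.2 after Benjamini-Hochberg adjustment over 4 such tests). The smallest p that 3 libraries against 3 allow is 0.1.

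A single contig of 3886 bp, the most abundant over the asymbiotic libraries and singled out after its values were seen, took 4.50% ± 0.195 (SD, n = 3) of the asymbiotic reads. In the mycorrhizal libraries it took 5.60% of the reads in replicate 1, 0.374% in replicate 2 and 0.760% in replicate 3. The test did not separate the groups in this share (two-sided exact permutation p = 0.4, adjusted 0.4).

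Some contigs were read in one kind of protocorm alone. With at least 10 reads in each of the 3 asymbiotic libraries and none in any mycorrhizal library, 1061 contigs were found in asymbiotic protocorms alone, with a median length of 390 bp. They were of low abundance, with a median of 54 reads per library, and held 0.109% ± 0.0306 of the asymbiotic reads (SD, n = 3). The most abundant of them, 732 bp long, stood at 62.0 ± 25.9 CPM (SD, n = 3). With a floor of 3 reads per library, which covers counting error alone, it was at least 4024-fold higher in asymbiotic than in mycorrhizal protocorms. The reverse pattern was found for 97 contigs, with a median length of 253 bp and a median of 531 reads per library. They held 0.259% ± 0.0453 of the mycorrhizal reads (SD, n = 3). The most abundant of these, 218 bp long, stood at 836 ± 350.1 CPM (SD, n = 3). By the same floor it was at least 27689-fold higher in mycorrhizal than in asymbiotic protocorms. Counts of 0 were more frequent than counting error gives, so neither fold is a firm lower bound. In asymbiotic replicate 2, 8.74% of contigs with a mean of 100 to 300 reads in the other 2 asymbiotic libraries had no read. EdgeR called 26 of the 1061 contigs and 35 of the 97. The reference is stated to come from asymbiotic reads, which would make the 2 numbers unlike by construction. The 97 contigs without an asymbiotic read go against that statement, if the same reads were assembled and counted. How the reference shaped the 2 numbers therefore stays open. Contigs of few reads were also often missed within a group. Of contigs with a mean of 10 to 100 reads in the other 2 mycorrhizal libraries, 25.7%, 33.9% and 83.4% had no read in mycorrhizal replicates 1, 2 and 3. With 20 reads asked for in place of 10, 608 contigs were found in asymbiotic protocorms alone. Among contigs of at least 500 bp, 329 were found in asymbiotic and 2 in mycorrhizal protocorms alone. Leaving a library out removes a condition, so the numbers can then stay or grow but not shrink. Contigs found in asymbiotic protocorms alone numbered 1842, 4962 and 2328 without asymbiotic replicate 1, 2 or 3, and 2785 and 1916 without mycorrhizal replicate 1 or 2. Contigs found in mycorrhizal protocorms alone numbered 667 and 210 without asymbiotic replicate 1 or 3, and 943 without mycorrhizal replicate 3.

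Where more than 1 contig of a Trinity gene was called, the calls mostly went one way. The 843 called contigs belonged to 767 Trinity genes, and 54 of these had more than 1 called contig. In 38 all called contigs were higher and in 14 all were lower, and 2 genes had calls in both directions. Contigs of one gene can share reads, so their calls are not independent. When reads were summed per Trinity gene before the test, edgeR called 1455 genes higher and 1045 lower in mycorrhizal protocorms. Of the 843 contigs, 762 lay in a Trinity gene that was called in the same direction, and 2 in one called in the other direction. A further 1807 of the 2500 called Trinity genes held no called contig. Summing contigs does not account for all of these. Trinity genes of a single contig made up 1180 of the 2500, more than the called genes with a called contig. Some were thus called on counts that were not called as a contig. The fit differed too, with 57152 Trinity genes tested.

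Reads on the assembly per library averaged 196182990 ± 20897876 in mycorrhizal and 100282092 ± 11186782 in asymbiotic protocorms (SD, n = 3 each; two-sided exact permutation p = 0.1, adjusted 0.2). At an equal depth of 87991285 reads, 89617 ± 34384 contigs had a read in mycorrhizal and 124067 ± 39776 in asymbiotic libraries (SD, n = 3 each). The test did not separate the groups (two-sided exact permutation p = 0.4, adjusted 0.4), and with 3 libraries each it has little power. Within each group the number varied widely. Before the depths were made equal, 164346, 83622 and 126093 contigs had a read in asymbiotic replicates 1 to 3, and 116372, 108857 and 51806 in mycorrhizal replicates 1 to 3. Of the contigs with a mean of 100 to 300 reads in the other 2 mycorrhizal libraries, 59.0% had no read in mycorrhizal replicate 3. The same share, relative to the other 2 libraries of each library's group, was 5.28% in mycorrhizal replicate 1, 7.20% in mycorrhizal replicate 2, 0.541% in asymbiotic replicate 1, 8.74% in asymbiotic replicate 2 and 0.999% in asymbiotic replicate 3. Of contigs with a mean of 10 to 100 reads in the other 2 libraries, 61.3% had no read in asymbiotic replicate 2, against 15.8% in asymbiotic replicate 1 and 30.1% in asymbiotic replicate 3.

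**Figure D3:**
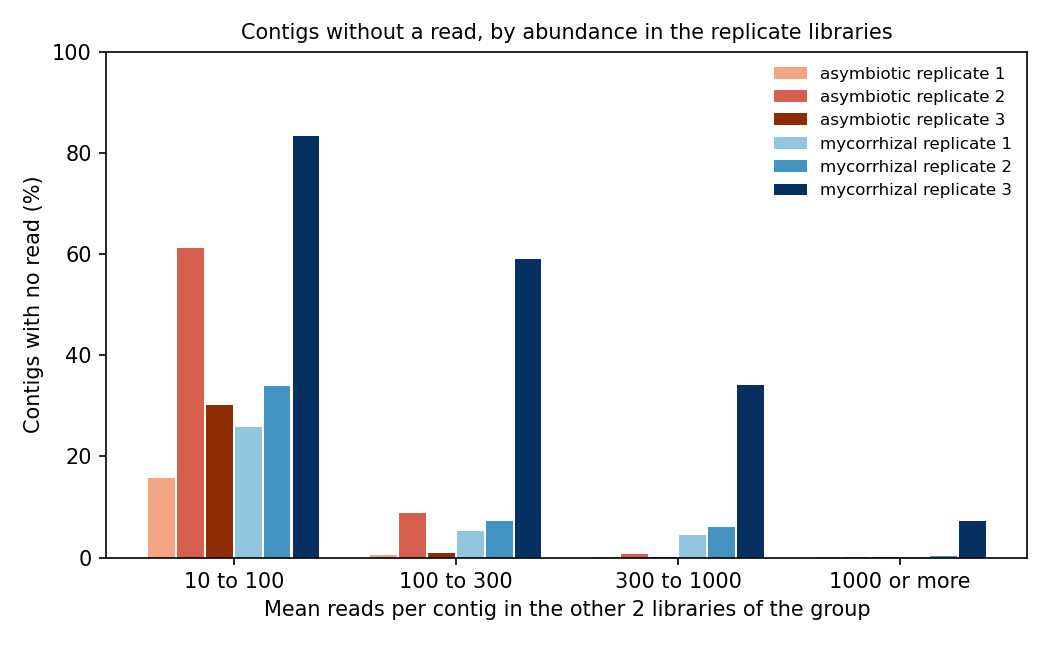
Share of contigs with no read in a library (percent), for contigs grouped by their mean reads in the other 2 libraries of the same group. Each bar is 1 library; mycorrhizal replicate 3 lacked reads for 59.0% of contigs with 100 to 300 mean reads and for 7.16% of those with 1000 or more.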

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

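Of the alternatives, the calls with unique reads, contigs of at least 500 bp, quality weights, the 2 libraries left out together and the dominant cluster removed were chosen after seeing the data. The differences in reads per library, in the share of the 100 leading contigs and in contigs with a read kept their direction. This held under all 7, 9 and 8 alternatives run, and the 4 named contigs kept their sign. In reads per library and in the share of the 100 leading contigs the groups did not overlap. Leaving 1 library out could thus not reverse these differences. The named contigs were chosen without overlap, so the same holds for their sign. The fit on unique reads gave 1 of the 793 called contigs it tested the opposite sign. Of 25 alternatives, 14 left the number of contigs called higher within 1.5 times of 611 and 13 left the number called lower within 1.5 times of 232. Calls rose to 1617 higher and 841 lower with no filter on low counts, 1831 and 2176 with DESeq2, 1455 and 1045 when reads were summed per Trinity gene, and 984 and 736 per Trinity cluster. Unique reads gave 1119 and 613 and limma-voom with quality weights 1461 and 654. Contigs of at least 500 bp gave 298 and 96, with 393 of the 615 called contigs of that length called again. Leaving out mycorrhizal replicate 3 and asymbiotic replicate 2 together gave 96 and 16. Limma-voom gave 206 higher, a test against 1.5-fold gave 130 lower, and the fit with no robust option gave 120 lower. With 1 library left out, calls ranged from 381 to 1176 higher and from 100 to 721 lower. The highest numbers came without mycorrhizal replicate 3, the fewest higher calls without mycorrhizal replicate 2 and the fewest lower calls without asymbiotic replicate 2. From 433 to 811 of the 843 contigs were called again in these fits. The cause of these changes was not tested. Upper-quartile scaling moved the median log2 fold change of all contigs from -0.06 to -0.23, and 64.0% of calls were then higher, against 72.5% with TMM. With the replicate block the test called 620 higher and 259 lower, 688 of the 843 among them, and the rising contigs TRINITY_DN70602_c0_g1_i2 and TRINITY_DN52117_c0_g1_i1 were not called (edgeR adjusted p = 0.875 and 0.853, within ranges of 1.09e-20 to 0.875 and 4.13e-18 to 0.853 over all alternatives, the lowest from DESeq2), at log2 fold changes of 11.89 and 12.10. Same-numbered libraries deviated from their group means with correlations of 0.08, -0.07 and -0.05. Asymbiotic replicate 2 and mycorrhizal replicate 3 dominated these deviations, so the values cannot exclude a pairing of the samples by number. Contigs read in asymbiotic protocorms alone fell from 1061 to 608 when 20 reads were asked for and to 329 at 500 bp or more, and ranged from 1113 to 4962 with 1 library left out. Contigs read in mycorrhizal protocorms alone fell from 97 to 2 at 500 bp or more and ranged from 127 to 943 with 1 library left out. With 1 library left out, the difference in reads per library ranged from 85810385 to 106674720 reads, that in the share of the 100 leading contigs from -9.29 to -5.69 percentage points, and that in contigs with a read at equal depth from -54673 to -14700. Depth limits contigs of few reads, where a count of 0 allows up to 0.0139 to 0.0341 CPM. With every library thinned to 87991285 reads, edgeR called 522 contigs higher and 193 lower.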

Other observations

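The sums per Trinity gene were planned. The other scalings, equal depth, DESeq2 and limma-voom were planned settings too, but their use to weigh the excess of higher calls was chosen after that excess had been seen. The tests of fewer reads, shared reads, carry-over and other splits of the libraries, and the fit with quality weights, were also chosen after the results they bear on had been seen, and the test of carry-over was revised after its value had been seen. The test of summed reads in mycorrhizal replicate 3 was set beforehand, although the contigs without reads had been seen.

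Trinity genes of a single contig made up 1180 of the 2500 called when reads were summed per Trinity gene. Of the contigs called over 100-fold higher in mycorrhizal protocorms, 126 had asymbiotic reads. Their asymbiotic reads were a median of 0.0895% of their mycorrhizal reads, from 0.00995% at the 10th to 0.356% at the 90th percentile of these contigs.

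Mycorrhizal replicate 3 had reads on 51806 contigs, and the other 2 mycorrhizal libraries on 116372 and 108857; a shortage of reads is argued against, since at one depth it had 47.3% of the contigs of the lower of the other 2. A candidate explanation is that few distinct molecules entered this library and were amplified: contigs with a mean of 100 to 300 reads in the other 2 libraries held 136% of their scaled summed reads there although 59.0% of them had no read. The sum alone does not set this library apart, since the same sum was 143% in each of the other 2, and among contigs of 1000 or more mean reads it was 72.7% in replicate 3. The question also stays open for asymbiotic replicate 2, where contigs of 10 to 100 mean reads held 99.7% of their scaled summed reads while 61.3% had none. The labels give no difference between the 3 mycorrhizal samples, so no biological explanation was tested.

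The series text describes a reference assembled from asymbiotic reads, yet 5994 contigs had mycorrhizal reads and no asymbiotic read, with a median length of 251 bp, and 97 of them had at least 10 reads in each mycorrhizal library. Loss of asymbiotic reads to similar contigs is argued against for most of the 97, as 78.4% had over 90% unique reads, while 14 had under 50%. The source of the asymbiotic reads was also examined for contigs over 100-fold higher as a set. Carry-over from the mycorrhizal libraries is argued against only at a single rate and with counting error alone. Contigs with over 90% unique reads allow a rate of at most 0.00312% by counting error, corrected for the number of contigs. Of the contigs called over 100-fold higher, 77 had enough mycorrhizal reads for 1 asymbiotic read to lie under that limit. Their median, with those at 0 included, was 26.3 times the limit. With the contig that sets the limit left out it was 9.45 times, under the 10 times set for this test. The spread between replicates is larger than counting error, and rates that differ between libraries were not tested. Carry-over of these kinds, and for single contigs, stays open. Whether contigs of either set, or other called contigs, come from the fungus was not tested, and no sequences were used here. Nor was it tested whether they come from plant genes that differ with the fungus or with the medium.

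Of the 843 calls, 72.5% were higher in mycorrhizal protocorms. The scaling of the libraries is argued against as the cause, since the share was 64.0% or more under 3 other scalings, and so is the greater depth of the mycorrhizal libraries, since it was 73.0% at one depth. Summed per Trinity gene or cluster, 58.2% and 57.2% of the calls were higher, so the share was smaller there. The choice of variance model may contribute, as the share on the same counts was 45.7% with DESeq2 and 40.3% with limma-voom, but it was 69.1% with limma-voom and quality weights. In the simulations at the real dispersions, 740 of 769 and 766 of 853 DESeq2 calls were unchanged contigs. For edgeR these were 7 of 8 and 27 of 98. For limma-voom they were 25 of 92 with changes in contigs of at least 10 CPM, and it made 0 calls at any abundance. The simulations give no error rate of the real calls, so they do not decide between the tools' shares. A difference between the tissues stays open and untested.

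The 6 libraries can be split into 3 and 3 in 10 ways, which are too few for a share under 0.05. The real split gave 611 contigs higher and 232 lower, and it was the only 1 of the 10 with as many in either direction. The highest number of edgeR calls in another split was 0, with 831 to 4633 contigs at an unadjusted p under 0.05 against 7787 in the real split. Every other split has libraries of both groups on each side, so a difference between the groups adds to the spread within a side. These splits therefore cannot show how many calls arise without a difference. DESeq2 and limma-voom were not run on the other splits.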
